A study of Mus musculus with 9 samples.

How the data were processed

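RNA from RAW264 control cells and from 2 clones with a CRISPR/Cas9 mutation in Zscan10 was sequenced on an Illumina MiSeq, 3 libraries per group and 9 in all. Per the labels total RNA was extracted, treated with DNase and made into stranded mRNA libraries. The submitters' notes name TopHat2 2.0.22, Cufflinks 2.1.1, featureCounts 1.4.6, edgeR 3.20.1 and mm10, with no role or order. The deposited table of all 9 libraries holds a normalised signal: gene counts that the authors divided by 1 size factor per library, TMM by its name. All of its values (100% in each library) were whole multiples of a step per library within 1e-06, so the reads behind them were recovered. The deposited tables of each pair of groups hold FPKM values (fpkm) scaled by the authors within each table. The authors' p-values (p_value columns) and q-values stand in the same deposited tables and were used only where named. Columns were matched to samples by the sample names in the labels.

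Depth was 1821703 to 2458539 recovered reads per library, and the 3-read limit beside a count of 0 covers counting error only, since the reads carry no molecular identifiers. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2 of the normalised reads plus 1, with all 9 libraries in 1 fit with a term for group, for genes with a value of at least 10 in at least 3 libraries. Calls had a Benjamini-Hochberg adjusted p under 0.05 in 1 contrast. The plan written before the data were examined set edgeR for counts and this limma test for normalised values. The filter was set once the values were known to be normalised, before results were seen. For a group with 0 reads a fold is a lower bound against 3 reads over the group, and with 1 to 3 reads a ratio with its 95% counting interval is given.

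Before the data were examined 31 gene lists with 816 genes were fixed, and the 22 lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, adjusted over the lists of 1 contrast. The rule for named genes was fixed then too. It took Zscan10 and Hp, up to 8 genes per direction for each clone, 8 per direction shared by both clones, 5 per direction between the clones and up to 4 members per list and contrast. Genes named by size of change needed a mean of at least 10 CPM in the higher group and libraries that did not overlap. Some genes the rule took are not reported here. The genes of the authors' short table are named for that table.

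Alternatives planned before the data were examined were other size factors, other filters, a pseudocount of 0.1, DESeq2 1.42.0 and limma-voom on the recovered reads, fits of only the groups compared, a block for replicate number, leaving out each library, thinning, an adjusted p under 0.01, edgeR 4.0.16 against a fold of 1.5 (which changes tool and threshold together), and for lists an estimated correlation and fry. The block was planned in edgeR and run in limma. Added after seeing the data were edgeR's quasi-likelihood test, limma on the FPKM tables (FPKM of at least 1 in 3 libraries, which changes values and samples together), and leaving out chromosome 12 and chromosome 16 beyond 70 Mb. No sign of pairing by replicate number was seen: residuals of libraries with the same number in different groups had correlations of -0.017 to 0.028. Residuals held little beyond counting error, so a shared day or culture could go unseen.

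The procedure was tested on simulated data. Of genes changed 1.3-fold it recovered 44%, 2-fold 90%, 4-fold 100% and 8-fold 98%, with 3 unchanged genes called. With 1 list raised 2-fold it called that list and 1 other, which was false. A chromosome raised 1.2-fold had a median log2 change of 0.26. Genome positions are from the mm10 annotation. Raw reads, guide sequences and genomic sequence were not analysed here.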

Results

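The series holds 9 Illumina RNA-seq libraries from RAW264, a mouse macrophage-like line that can form osteoclasts, the cells that resorb bone, when given the cytokine RANKL. Per the labels none of these cultures received RANKL. Control cells and 2 clones in which the zinc finger gene Zscan10 was mutated with CRISPR/Cas9 had 3 libraries each, and the clones are called KO1 and KO2 here. Per the sample characteristics KO1 carries its mutation in exon 2 and KO2 in exon 5, and the column names of the deposited values carry the same numbers. The names given to the raw reads of these libraries carry the opposite numbers, so which clone is mutated in which exon stays open. By its title the series concerns a restraint that Zscan10 puts on osteoclast formation through inhibitory factors, so each clone was compared with control and the clones with each other. Between 1821703 and 2458539 reads per library were recovered, 19463573 in all. Of 23420 listed genes 13569 had a read and 9564 passed the filter on low values and were tested. Levels are given as mean ± SD of 3 libraries in normalised reads, and log2 changes ± SE on the log2(value + 1) scale, which understates changes of genes with few reads. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. That spread was small. Between libraries of 1 group the chi-square per degree of freedom of the recovered reads was 1.06 to 1.32, where 1 would be counting error alone. Whether the libraries of a group were separate cultures or repeats of 1 sample stays open.

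Zscan10, the targeted gene, had 0 reads in all 9 libraries, controls included. It lies on the plus strand of chromosome 17 from 23600856 to 23611019 in mm10, with 6 exons, of which exon 2 spans 23605505 to 23605964 and exon 5 spans 23608108 to 23608165. A count of 3 reads would correspond to 0.154 CPM (counts scaled to the library total) over all libraries and to 1.22 to 1.65 CPM in single ones, limits that cover counting error only. Expression of Zscan10 was not detectable at this depth, and the reads check neither the knockout labels nor the exon assignment.

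Haptoglobin (Hp; chromosome 8, 109575128 to 109579172, minus strand), the plasma protein that binds free haemoglobin, was nearly lost from KO1: 56.2 ± 11.4 normalised reads in control against 0.339 ± 0.587 in KO1, where 1 read was seen against 176, a ratio of 167-fold (95% counting interval 29.6 to 6628). The lysosomal protease gene Ctsh (chromosome 9, 90054267 to 90076095) fell from 255 ± 1.46 to 2.35 ± 2.29, 109-fold, and 250-fold without KO1 replicate 2. The laminin gene Lama4 (chromosome 10, 38965515 to 39110188) and the sodium channel gene Scn11a had 0 reads in KO1 against 59.6 ± 7.21 and 51.2 ± 3.9 in control, at least 58.5-fold and 50.6-fold lower. In the other direction Tfec, a transcription factor of the same family as Mitf, went from 0 reads in control to 34.2 ± 12, at least 35.5-fold higher. The interferon-induced genes rose together in KO1, with a median log2 change of 2.36, where 41 of 41 tested members rose and 0 fell, or 41 and 0 adjusted over the list alone.

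Among the interferon list of KO1, Ifi44 rose 7.26-fold from 134 ± 7.02 to 975 ± 18.3, Ifit1 17.4-fold from 3.28 ± 1.74 to 56.9 ± 4.55 and Parp14 4.48-fold from 135 ± 2.46 to 604 ± 23.2. The list had a camera adjusted p of 4.05e-70, and of 5.84e-05 with an estimated correlation. Genes of MHC class I antigen presentation also rose, median 0.58, adjusted p = 8.47e-08. In the MHC class I list 9 of 15 tested members rose and 0 fell, or 11 and 0 adjusted over the list alone. The peptide transporter gene Tap1 rose 2.37-fold to 127 ± 3.65 and Tapbp 1.67-fold to 356 ± 11.5. Oasl2, Apol9a, Ifi202b, H2-T23 and H2-D1, which also rose in this clone, belong to families of closely related copies, and no fold is given for them because reads of such copies can be assigned to the wrong member.

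Macrophage identity genes lay higher in KO1 as a list, median 0.43, adjusted p = 9.31e-15. In the macrophage list 17 of 26 tested members rose and 3 fell, or 17 and 4 adjusted over the list alone. The scavenger receptor gene Cd36 rose 2.36-fold from 814 ± 64 to 1923 ± 20.3, whereas the inhibitory Fc receptor gene Fcgr2b fell 6.59-fold from 218 ± 21.6 to 33.1 ± 5.33. For osteoclast effector and fusion genes 9 of 19 tested members rose and 3 fell, or 10 and 3 adjusted over the list alone, median 0.22, adjusted p = 2.92e-05. Carbonic anhydrase 2 (Car2), which acidifies the resorption space, rose 1.87-fold to 2813 ± 97.1 and integrin alpha V (Itgav) 2.17-fold to 519.9 ± 36.2. Osteoclast differentiation drivers were not called as a list, adjusted p = 0.626. In the osteoclast drivers list 5 of 31 tested members rose and 4 fell, or 6 and 4 adjusted over the list alone. Among the drivers Tnfrsf11a, which encodes the RANKL receptor RANK, rose 1.69-fold to 429 ± 13.7, Fos 1.93-fold to 128 ± 15.7 and Mitf 1.52-fold to 269 ± 23. Osteoclast inhibitory factors, the class named in the series title, were not called as a list in KO1, median 0.072, adjusted p = 0.142. In the osteoclast inhibitory factors list 9 of 31 tested members rose and 5 fell, or 9 and 6 adjusted over the list alone. Within it Hp fell while Lgals9 (galectin-9) rose 3.7-fold to 324 ± 16.9.

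Cholesterol biosynthesis genes fell in KO1, median -0.38, adjusted p = 2.62e-08, with Idi1 lower by 1.47-fold and Hmgcs1 by 1.43-fold. In the cholesterol list 0 of 22 tested members rose and 16 fell, or 0 and 17 adjusted over the list alone. In the list of LXR targets 0 of 10 tested members rose and 5 fell, or 0 and 6 adjusted over the list alone, median -0.38, adjusted p = 5.49e-05, and its largest falls were in genes of fatty acid desaturation, Scd1 by 3.09-fold and Scd2 by 2.01-fold. For NRF2 targets 10 of 21 tested members rose and 1 fell, or 12 and 2 adjusted over the list alone, median 0.19, adjusted p = 2.94e-06, and haem oxygenase 1 (Hmox1) rose 3.1-fold from 318 ± 19.2 to 984 ± 56.8. Haem, iron and acute phase genes lay higher by median (0.26) and by test (adjusted p = 0.000112) and lower by mean (-0.049), with Hp among the fallers, and 7 of 13 tested members rose and 2 fell, or 7 and 3 adjusted over the list alone. Lysosomal genes likewise lay higher by median (0.093) and test (adjusted p = 0.00134) and lower by mean (-0.039), with Ctsh among the fallers, and 14 of 37 tested members rose and 3 fell, or 15 and 3 adjusted over the list alone. Chaperone and stress genes of the unfolded protein list lay higher (adjusted p = 0.000217, adjusted p = 0.104 with an estimated correlation), with Hyou1 up 1.28-fold and the serine synthesis gene Phgdh down 2.05-fold. In the unfolded protein list 15 of 28 tested members rose and 3 fell, or 15 and 3 adjusted over the list alone. Cytosolic ribosomal protein genes fell by small amounts, median -0.16, adjusted p = 1.84e-19. In the ribosomal list 0 of 43 tested members rose and 39 fell, or 0 and 41 adjusted over the list alone.

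Position on the chromosome moved with some of these groups in KO1. The 347 tested genes of chromosome 12 had a median log2 change of -0.28 (152 fell and 15 rose), and Rps7 and Rps29, the largest falls of the ribosomal list, lie there. The 62 tested genes of chromosome 16 beyond 70 Mb had a median of -0.80 (48 fell and 5 rose). Oxidative phosphorylation genes were lower (median -0.11, adjusted p = 0.00022, adjusted p = 0.104 with an estimated correlation), and their largest falls, Atp5o (2.36-fold) and Atp5j (2.31-fold), lie in that part of chromosome 16. In the oxidative phosphorylation list 0 of 36 tested members rose and 8 fell, or 1 and 13 adjusted over the list alone.

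Over all tested genes 1985 differed between KO1 and control, 1008 higher and 977 lower, by limma at a Benjamini-Hochberg adjusted p below 0.05 over 9564 genes. Lists were compared with the other genes by camera with a preset correlation. With an estimated correlation their calls in this comparison held at larger p, except those of oxidative phosphorylation and the unfolded protein list. DESeq2 on the recovered reads called 1236 genes and edgeR against a fold of 1.5 called 349. Not called in KO1 were the lists of NF-kB targets and cytokines, MHC class II presentation, S phase, G2 and M phase, glycolysis and hypoxia, p53 targets, immediate early genes and adhesion and podosomes. In the NF-kB list 3 of 20 tested members rose and 7 fell, or 4 and 8 adjusted over the list alone (adjusted p = 0.279). In the MHC class II list 1 of 7 tested members rose and 2 fell, or 2 and 2 adjusted over the list alone (adjusted p = 0.552). In the S phase list 2 of 32 tested members rose and 2 fell, or 1 and 2 adjusted over the list alone (adjusted p = 0.855). In the G2 and M phase list 0 of 32 tested members rose and 5 fell, or 0 and 5 adjusted over the list alone (adjusted p = 0.279). In the glycolysis list 6 of 30 tested members rose and 1 fell, or 6 and 1 adjusted over the list alone (adjusted p = 0.19). In the p53 list 6 of 25 tested members rose and 2 fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.0739). In the immediate early list 4 of 19 tested members rose and 5 fell, or 4 and 5 adjusted over the list alone (adjusted p = 0.728). In the adhesion list 8 of 30 tested members rose and 4 fell, or 9 and 6 adjusted over the list alone (adjusted p = 0.279). Median, mean and test differed in sign for the uncalled lists of osteoclast drivers (median -0.035, mean 0.054, test upward), MHC class II (median 0.14, mean -0.065, test downward) and S phase (median 0.043, mean -0.0041, test upward).

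**Figure D1:**
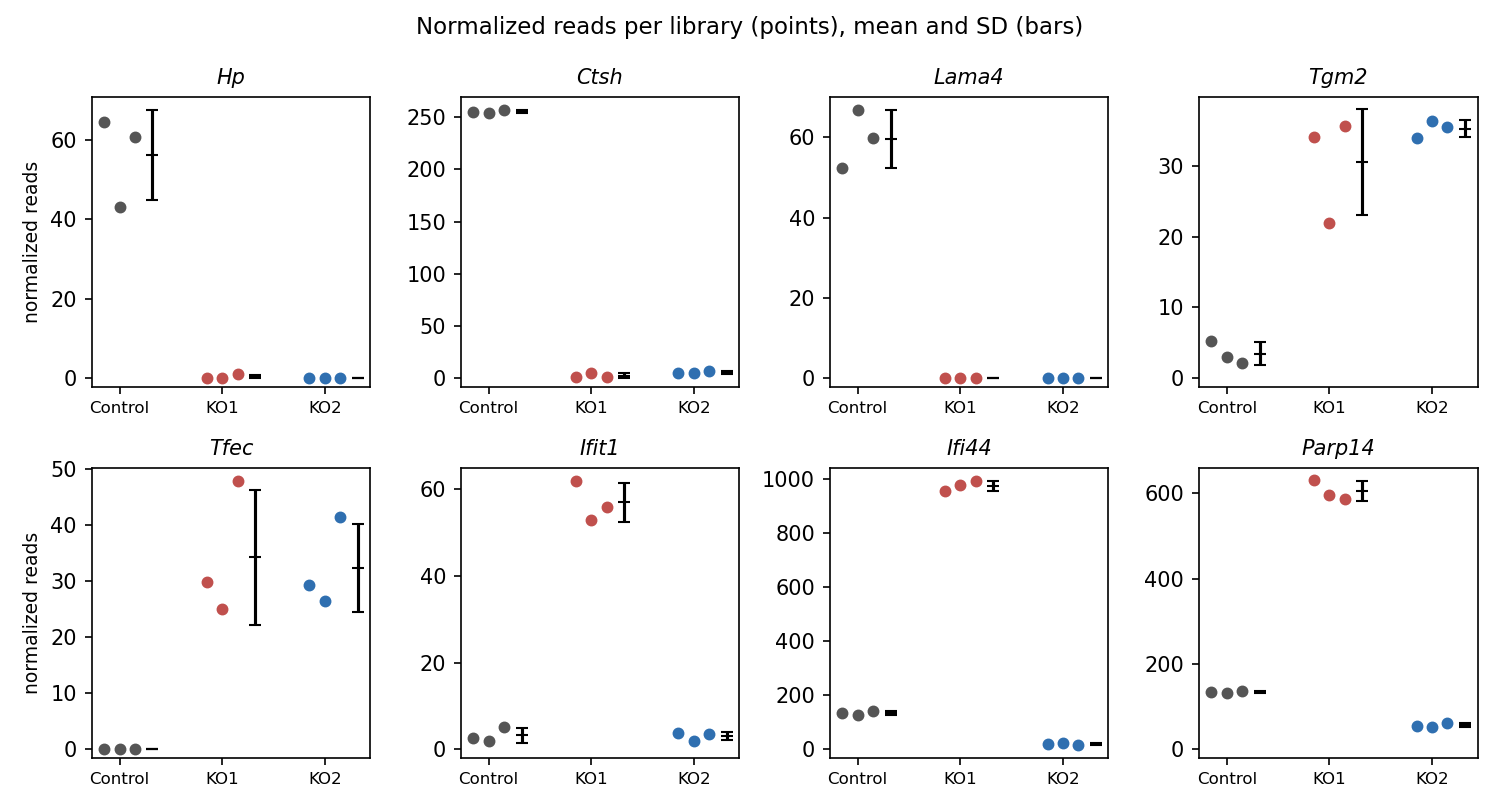
Normalised reads of 8 named genes in each library (points; y axis, linear scale from 0; x axis, group), with the mean and SD of 3 libraries as bars. Hp, Ctsh and Lama4 were near 0 in both clones, Tgm2 and Tfec were higher in both, and Ifit1, Ifi44 and Parp14 were higher in KO1, with Ifi44 at 975 ± 18.3 in KO1 and 20.2 ± 4.63 in KO2.

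In KO2 Hp had 0 reads in 3 libraries, at least 55.1-fold lower than the control level of 56.2 ± 11.4. Hpgd (chromosome 8, 56294552 to 56321046), which encodes the enzyme that inactivates prostaglandins, fell from 301 ± 14.3 to 0.393 ± 0.681, where 1 read was seen against 940, a ratio of 882-fold (95% counting interval 158 to 34876). Ceruloplasmin (Cp), the copper-carrying ferroxidase, fell 36.6-fold from 201 ± 11 to 5.49 ± 0.517, and the surface glycoprotein gene Cd24a 82.1-fold from 138 ± 11.3 to 1.68 ± 0.432. Nfatc1, the transcription factor that drives osteoclast differentiation, rose 3.4-fold from 164 ± 12.7 to 559 ± 34.1 (log2 change 1.76 ± 0.076, adjusted p = 1.20e-27), and Acp5, which encodes the osteoclast enzyme tartrate-resistant acid phosphatase, rose 17.1-fold from 1.85 ± 1.61 to 31.7 ± 1.2. The interferon-induced genes fell, median -1.10, or -1.09 with the 6 members at 3 reads or fewer in a group held at that floor. In the interferon list 0 of 41 tested members rose and 33 fell, or 0 and 35 adjusted over the list alone.

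Within the interferon list of KO2, Usp18, a brake on interferon receptor signalling, fell 8.81-fold from 51.6 ± 4.68 to 5.86 ± 3.0 and Ifi44 6.64-fold to 20.2 ± 4.63 (list adjusted p = 4.11e-22). MHC class I genes were lower (median -0.46, adjusted p = 8.04e-05), with B2m down 1.63-fold to 776 ± 37.1. In the MHC class I list 1 of 15 tested members rose and 9 fell, or 1 and 10 adjusted over the list alone. NF-kB targets and cytokines were lower (median -0.29, adjusted p = 0.00195), with the chemokine gene Ccl4 down 2.49-fold to 33.5 ± 4.72. In the NF-kB list 3 of 20 tested members rose and 10 fell, or 3 and 10 adjusted over the list alone. In the MHC class II list 0 of 7 tested members rose and 3 fell, or 0 and 3 adjusted over the list alone, adjusted p = 0.00492 and adjusted p = 0.0501 with an estimated correlation, and the invariant chain gene Cd74 fell 3.07-fold to 184 ± 10.1.

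Osteoclast inhibitory factors were lower in KO2 as a list, median -0.14, adjusted p = 0.0193. In the osteoclast inhibitory factors list 6 of 31 tested members rose and 12 fell, or 6 and 14 adjusted over the list alone. That call was lost with the correlation estimated (adjusted p = 0.0654 with an estimated correlation) and without Control replicate 2 (adjusted p = 0.0595). Lgals9 fell 5.5-fold to 15.9 ± 3.39 and the inhibitory receptor gene Lilrb4 1.94-fold to 162 ± 18.2, while Nrp1 had 3 reads in KO2 against 108, a ratio of 33.8-fold (95% counting interval 11.3 to 166). Rcan1, which inhibits calcineurin and lies on distal chromosome 16, went the other way, up 5.57-fold to 361 ± 4.64. Among the differentiation drivers 7 of 31 tested members rose and 9 fell, or 10 and 9 adjusted over the list alone, adjusted p = 0.119, so the list was not called, although Fos rose 3.43-fold to 227 ± 12.8 and Tnfrsf11a 1.99-fold to 505 ± 17. Effector and fusion genes were higher (median 0.16, adjusted p = 0.000317), with Itgav up 2.08-fold and Adam8 1.65-fold, whereas Car2 fell 1.77-fold to 851 ± 17.4. In the osteoclast effectors list 8 of 19 tested members rose and 1 fell, or 9 and 1 adjusted over the list alone.

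The unfolded protein list was lower in KO2, median -0.37, adjusted p = 2.40e-22, with Hspa5 down 1.53-fold from 5716 ± 129 and Pdia4 1.92-fold from 852 ± 29.8. In the unfolded protein list 0 of 28 tested members rose and 20 fell, or 0 and 20 adjusted over the list alone. Macrophage identity genes were higher (median 0.20, adjusted p = 0.000317), with lipoprotein lipase (Lpl) up 2.34-fold to 6551 ± 216 and Cd36 2.56-fold to 2084 ± 76.8. In the macrophage list 12 of 26 tested members rose and 7 fell, or 14 and 7 adjusted over the list alone. NRF2 targets lay higher (median 0.081, adjusted p = 0.000108), for example Gclm by 1.6-fold and Taldo1 by 1.78-fold. In the NRF2 list 9 of 21 tested members rose and 2 fell, or 9 and 3 adjusted over the list alone. In the LXR list 1 of 10 tested members rose and 6 fell, or 1 and 6 adjusted over the list alone, adjusted p = 0.00515 and adjusted p = 0.0879 with an estimated correlation, with the efflux transporter gene Abcg1 down 2.44-fold. Glycolysis and hypoxia genes lay slightly higher (median 0.085, adjusted p = 0.0162, adjusted p = 0.403 with an estimated correlation, and 0.0738 without Control replicate 2), with Ldha up 1.2-fold. In the glycolysis list 9 of 30 tested members rose and 4 fell, or 11 and 5 adjusted over the list alone. Ribosomal protein genes lay slightly lower (median -0.057, adjusted p = 0.00715, adjusted p = 0.491 with an estimated correlation, and 0.0569 without Control replicate 1). In the ribosomal list 1 of 43 tested members rose and 9 fell, or 1 and 11 adjusted over the list alone.

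Chromosome 12 genes lay higher in KO2, with a median log2 change of 0.28 over 347 genes (157 rose and 13 fell), and Fos, Jdp2, Npc2 and Ltbp2 lie on it. Ltbp2 went from 0 reads in control to 50.2 ± 6.75, at least 51.9-fold higher, and Npc2 rose 1.98-fold to 839 ± 12.4. The distal part of chromosome 16 had a median of -0.020 in this clone.

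Of all tested genes 2152 differed between KO2 and control, 1020 higher and 1132 lower, in the same limma fit. DESeq2 called 1396 and edgeR against a fold of 1.5 called 421. With an estimated correlation the list calls held at larger p, except the calls for which that p is given above. The adjusted p was then 0.00185 for the interferon list and 0.00986 for the unfolded protein list. Uncalled in KO2 were the lists of S phase, G2 and M phase, cholesterol biosynthesis, oxidative phosphorylation, lysosome, haem and iron, p53 targets, immediate early genes and adhesion and podosomes. In the S phase list 4 of 32 tested members rose and 2 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.526). In the G2 and M phase list 2 of 32 tested members rose and 6 fell, or 3 and 6 adjusted over the list alone (adjusted p = 0.613). In the cholesterol list 1 of 22 tested members rose and 6 fell, or 1 and 6 adjusted over the list alone (adjusted p = 0.359). In the oxidative phosphorylation list 1 of 36 tested members rose and 9 fell, or 2 and 9 adjusted over the list alone (adjusted p = 0.36). In the lysosome list 10 of 37 tested members rose and 11 fell, or 12 and 12 adjusted over the list alone (adjusted p = 0.359). In the haem list 4 of 13 tested members rose and 4 fell, or 4 and 4 adjusted over the list alone (adjusted p = 0.86). In the p53 list 3 of 25 tested members rose and 3 fell, or 3 and 3 adjusted over the list alone (adjusted p = 0.991). In the immediate early list 5 of 19 tested members rose and 4 fell, or 6 and 4 adjusted over the list alone (adjusted p = 0.991). In the adhesion list 7 of 30 tested members rose and 9 fell, or 7 and 9 adjusted over the list alone (adjusted p = 0.679). Median, mean and test differed in sign for the uncalled lists of S phase (median -0.00022, mean 0.046, test upward), lysosome (median -0.042, mean -0.048, test upward), immediate early genes (median 0.027, mean -0.076, test downward) and adhesion (median -0.0060, mean 0.12, test upward).

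A set of genes moved the same way in both clones. Besides Hp, the named genes with shared falls included Ctsh (5.57 ± 1.31 in KO2, 45.9-fold lower), Lama4 and Scn11a (0 reads in either clone), Fmnl2 (0 reads in either clone against 25.3 ± 5.92) and Hpgd, which fell 14.8-fold to 20.2 ± 5.93 in KO1. The shared rises included Tfec (32.4 ± 7.87 in KO2, at least 33-fold higher), the transglutaminase gene Tgm2 (up 8.91-fold in KO1 and 10.3-fold in KO2 from 3.43 ± 1.62), the collagen gene Col18a1 (4.76-fold and 10.7-fold from 10.3 ± 4.29) and the chemokine gene Cxcl16 (4.3-fold and 3.95-fold from 59 ± 6.03). Tnfrsf11a and Itgav, described above, rose in both. The authors' deposited table of 9 singled-out genes lists Hp, Ptgfrn, Ctsh, Msrb3, Gypc, Ltb, Fcgr2b, Iqcg and Cd74, all of which fell in both clones by the limma fit, but they were chosen on these same libraries, which makes their direction no independent evidence.

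In all 720 genes were called in the same direction in both clones, 383 higher and 337 lower, against 107.5 and 116 expected of independent lists of the same sizes. Another 307 were called in opposite directions, against 224 expected. The number of shared genes alone does not separate an effect of the mutation from a control that stands apart, because the same count with each clone in the control's place was larger: 1009 genes set KO1 and 1224 genes set KO2 apart from both other groups. The comparisons share their control libraries. Simulated unchanged groups against those controls gave at most 1 call in either comparison in each of 100 draws, 0 shared calls, a correlation of log2 changes across genes of 0.484 and a covariance of 0.0132. The observed correlation was 0.373 and the observed covariance 0.0990, where genes are not independent replicates, and with 3 control libraries no split leaves 2 in each part, so part of the excess may come from the shared controls. DESeq2 gave 430 shared calls and edgeR against a fold of 1.5 gave 116. The average of both clones against control called 1860 genes, 915 higher and 945 lower. The authors' own test of 6 knockout against 3 control libraries called 524 (233 higher and 291 lower). The limma average takes its spread within each of the 3 groups, so it can call genes that changed in 1 clone only. In the interferon list it called 22 of 41 tested members higher and 0 lower, though in KO2 0 rose and 33 fell. DESeq2 called 1126 for this average and edgeR against a fold of 1.5 called 255.

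**Figure D2:**
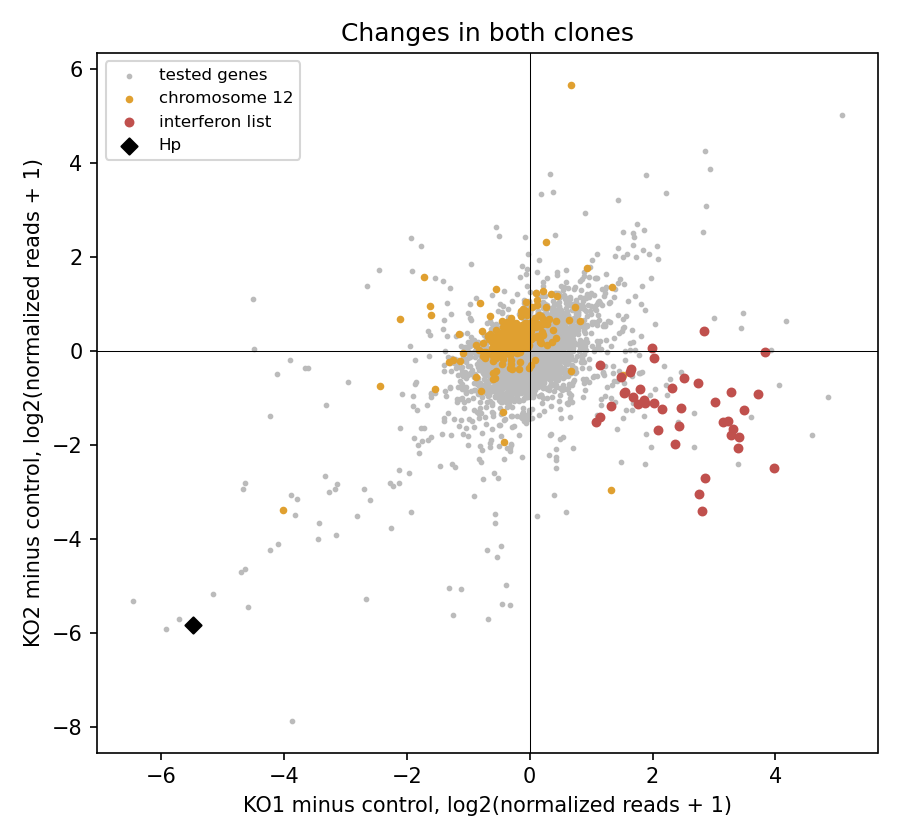
Log2 change in KO1 (x axis) and KO2 (y axis) against control, on the log2(normalised reads + 1) scale, for each of 9564 tested genes (points), with chromosome 12, the 41 tested interferon-induced genes and Hp marked. The interferon genes lie to the right in KO1 and mostly below 0 in KO2, and Hp lies low in both.

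Between the clones the largest median difference among the lists was in the interferon-induced genes, of which 41 of 41 were lower in KO2 than in KO1 (41 adjusted over the list alone), with a median log2 difference of -3.39 that did not change with low members held at the floor. Ifi44 was 48.2-fold lower in KO2, Ddx58, which encodes the RNA sensor RIG-I, 20.4-fold lower (19.4 ± 7.01 against 395 ± 21.7), and Usp18 60.4-fold lower. Nfatc1 was 3.51-fold higher in KO2, with 159 ± 5.98 in KO1. Single genes far apart included Psma8, with 0 reads in KO1 and 48.3 ± 5.3 in KO2 (at least 47.1-fold higher), Angptl2 (17.4-fold higher in KO2) and Cp (28.2-fold lower in KO2).

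The unfolded protein list was lower in KO2 than in KO1 (median -0.46, adjusted p = 1.55e-22), as were MHC class I genes (median -0.89, adjusted p = 1.93e-13) and osteoclast inhibitory factors (median -0.28, or -0.27 with low members at the floor, adjusted p = 0.0019). In the unfolded protein list 1 of 28 tested members were higher and 22 lower, or 1 and 23 adjusted over the list alone. In the MHC class I list 0 of 15 tested members were higher and 13 lower, or 0 and 15 adjusted over the list alone. In the osteoclast inhibitory factors list 5 of 31 tested members were higher and 15 lower, or 5 and 17 adjusted over the list alone. Lgals9 was 20.3-fold lower in KO2, and Rcan1 4.15-fold higher. Cholesterol biosynthesis genes were higher in KO2 than in KO1 (median 0.27, adjusted p = 0.000169). In the cholesterol list 11 of 22 tested members were higher and 1 lower, or 11 and 1 adjusted over the list alone. With an estimated correlation these calls held at larger adjusted p. It was 0.00667 for the unfolded protein list, 0.00203 for MHC class I, 0.0329 for osteoclast inhibitory factors and 0.0254 for cholesterol biosynthesis.

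Further lists were called with the preset correlation and not with an estimated one. NF-kB targets were lower in KO2 (adjusted p = 0.0459, adjusted p = 0.131 with an estimated correlation), as were MHC class II genes (adjusted p = 0.0212, adjusted p = 0.105 with an estimated correlation) and haem and iron genes (median -0.34, or -0.24 with low members at the floor, adjusted p = 0.0048, adjusted p = 0.0562 with an estimated correlation). In the NF-kB list 3 of 20 tested members were higher and 11 lower, or 4 and 11 adjusted over the list alone. In the MHC class II list 0 of 7 tested members were higher and 4 lower, or 0 and 4 adjusted over the list alone. In the haem list 2 of 13 tested members were higher and 6 lower, or 3 and 7 adjusted over the list alone. Macrophage identity genes tested lower, adjusted p = 0.0459 and adjusted p = 0.224 with an estimated correlation, with a mean of -0.17 but a median of 0.062, and 9 of 26 tested members were higher and 10 lower, or 11 and 10 adjusted over the list alone. Higher in KO2 were oxidative phosphorylation genes (adjusted p = 0.0315, adjusted p = 0.324 with an estimated correlation), with Atp5o and Atp5j on distal chromosome 16 leading, and ribosomal protein genes (adjusted p = 2.98e-07, adjusted p = 0.224 with an estimated correlation), with Rps7 and Rps29 on chromosome 12 leading. In the oxidative phosphorylation list 9 of 36 tested members were higher and 2 lower, or 9 and 2 adjusted over the list alone. In the ribosomal list 23 of 43 tested members were higher and 0 lower, or 26 and 0 adjusted over the list alone. The NF-kB call was also lost without KO1 replicate 3 (adjusted p = 0.0894), without Control replicate 3 (0.0504), without KO2 replicate 1 (0.0517) and without KO2 replicate 2 (0.0553). The macrophage call was lost without Control replicate 2 (0.0641), Control replicate 3 (0.0738), KO1 replicate 3 (0.0696) and KO2 replicate 3 (0.0517), and the oxidative phosphorylation call without KO1 replicate 1 (0.0638) and KO2 replicate 1 (0.0517).

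Lists not called between the clones were osteoclast drivers, osteoclast effectors, S phase, G2 and M phase, LXR targets, glycolysis and hypoxia, lysosome, NRF2 targets, p53 targets, immediate early genes and adhesion. In the osteoclast drivers list 9 of 31 tested members were higher and 4 lower, or 9 and 5 adjusted over the list alone (adjusted p = 0.279). In the osteoclast effectors list 7 of 19 tested members were higher and 5 lower, or 8 and 5 adjusted over the list alone (adjusted p = 0.757). In the S phase list 6 of 32 tested members were higher and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.638). In the G2 and M phase list 7 of 32 tested members were higher and 4 lower, or 8 and 4 adjusted over the list alone (adjusted p = 0.807). In the LXR list 3 of 10 tested members were higher and 1 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.189). In the glycolysis list 8 of 30 tested members were higher and 5 lower, or 10 and 5 adjusted over the list alone (adjusted p = 0.279). In the lysosome list 8 of 37 tested members were higher and 12 lower, or 8 and 14 adjusted over the list alone (adjusted p = 0.426). In the NRF2 list 7 of 21 tested members were higher and 7 lower, or 8 and 7 adjusted over the list alone (adjusted p = 0.925). In the p53 list 2 of 25 tested members were higher and 7 lower, or 3 and 8 adjusted over the list alone (adjusted p = 0.125). In the immediate early list 3 of 19 tested members were higher and 3 lower, or 3 and 3 adjusted over the list alone (adjusted p = 0.807). In the adhesion list 8 of 30 tested members were higher and 7 lower, or 9 and 10 adjusted over the list alone (adjusted p = 0.839). Median, mean and test differed in sign for the uncalled lists of osteoclast drivers (median -0.00060, mean 0.17, test upward), G2 and M phase (median -0.018, mean 0.0064, test upward) and NRF2 targets (median 0.035, mean -0.10, test upward).

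Between the clones 2533 genes differed, 1238 higher and 1295 lower in KO2, by the same limma fit, and all 307 genes with opposite calls against control were among them. DESeq2 called 1612 and edgeR against a fold of 1.5 called 461. Chromosome 12 genes were higher in KO2 than in KO1 by a median log2 of 0.57 (264 higher and 10 lower of 347). The genes of chromosome 16 beyond 70 Mb were higher by 0.89 (48 higher and 4 lower of 62). Of the 322 called results for named genes over the 3 comparisons, 136 were not called by edgeR against a fold of 1.5.

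**Figure D3:**
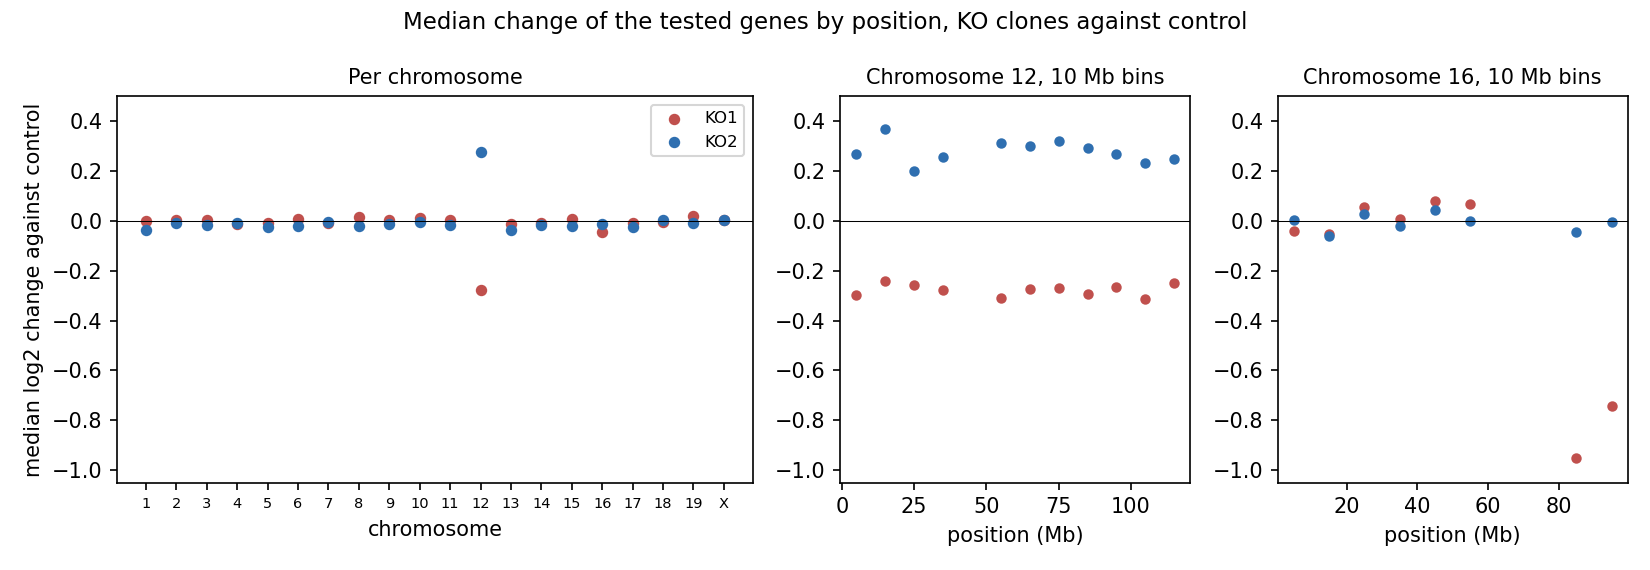
Median log2 change of tested genes against control in KO1 and KO2 (y axis), per chromosome (left, x axis chromosome) and in 10 Mb bins with at least 10 genes along chromosomes 12 and 16 (x axis position in Mb). Chromosome 12 stands at -0.28 in KO1 and 0.28 in KO2, and the distal end of chromosome 16 is low in KO1.

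The authors' deposited FPKM tables hold their own tests of the same comparisons. In the authors' deposited table of KO1 against control 1830 genes were called, in that of KO2 against control 2027 and in that of KO2 against KO1 2409. For Hp the authors' deposited table gave a q of 0.344 in KO1 and of 0.000441 in KO2, so that Hp was not called in KO1 there. For Hpgd the authors' deposited table gave a q of 0.000479 in KO1 and 0.373 in KO2, where 1 read was seen.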

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

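The tests chosen only after the result was seen were the 3 on chromosome 12, those of endotoxin, scaling and a single library for the interferon genes, and that of the control standing apart. Those of interferon transcripts, shared controls and other splits were written before.

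Chromosome 12 genes differed between clones by a median log2 of 0.57, KO2 minus KO1, with the difference itself tested by camera. Scaling is argued against: a size factor moves all genes of a library alike, while the medians of the 19 other chromosomes lay within 0.0437 of 0 in both clones. A few strong genes are argued against, since 94.2% of its genes lay above the median of the others. A candidate explanation is a difference in copies of the whole chromosome, for which all 11 bins lay above 0, the lowest at 0.381. Copy number was not measured. An effect shared by both Zscan10 mutations is argued against by the opposite medians, -0.28 in KO1 (152 fell, 15 rose) and 0.28 in KO2 (157 rose, 13 fell). An effect particular to 1 mutation stays open as untested.

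Interferon-induced genes differed by a median log2 of -3.39 (KO2 minus KO1). Scaling moves all genes of a library alike, and is argued against by an all-gene median of -0.0066 in KO1 beside 2.36 for the list. Under library-size scaling 41 members were still called higher, but the all-gene median moved only to -0.041, so few calls could be lost. A change in 1 library is argued against by 41 members with all KO1 libraries above all control libraries. Chance gives that separation for 10% of single genes in either direction, and these members are not independent of each other. Library medians over the control mean were 2.40, 2.21 and 2.35 in KO1 and -1.14, -1.0 and -1.16 in KO2. Transcripts of interferon genes in the KO1 cultures may play a part: 7 reads, all of Ifnb1, were seen over 19 listed interferon genes in KO1, against 0 in control and KO2. So few reads show no source. Endotoxin or another broad inflammatory stimulus stays open. The NF-kB list was not called in KO1 by camera (adjusted p = 0.279), and fry called it downward (unadjusted p = 0.00189). Neither test called it higher, but its members went both ways, 7 lower and 3 higher. An effect shared by both mutations is argued against, since 41 of 41 members rose in KO1 while in KO2 0 rose and 33 fell. Clonal variation and an effect particular to 1 mutation stay open as untested.

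The 720 genes called in the same direction in both clones leave open a control population that stands apart by itself. The control was set apart by 0.588 times as many genes as KO2, so the count does not single out the control. It neither shows nor excludes that explanation. Interferon genes that fell in KO2 add to the KO2 count, and the ratio was not computed without them. The size of the part of the shared control libraries stays open. The highest simulated number of shared calls was 0, but unchanged groups gave at most 1 call in either comparison of a draw, which left hardly a call to share. The observed covariance of log2 changes was 0.0990, above the highest simulated value of 0.0146. The simulated spread of the shared controls thus did not account for all of the covariance. An effect of losing Zscan10 in both clones stays open, as no test here separates it from differences between clones that arose by chance.

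Between the clones 10 other lists were called with the preset correlation, and 6 of them were not called with an estimated one: NF-kB targets (adjusted p = 0.131 with an estimated correlation), macrophage identity (adjusted p = 0.224 with an estimated correlation), MHC class II (adjusted p = 0.105 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.324 with an estimated correlation), haem and iron (adjusted p = 0.0562 with an estimated correlation) and ribosomal proteins (adjusted p = 0.224 with an estimated correlation). Median log2 differences, KO2 minus KO1, were -0.28 for osteoclast inhibitory factors, -0.39 for NF-kB targets, 0.062 for macrophage identity (tested lower), -0.46 for MHC class II, -0.89 for MHC class I, 0.27 for cholesterol biosynthesis, 0.046 for oxidative phosphorylation, -0.34 for haem and iron, -0.46 for the unfolded protein list and 0.098 for ribosomal proteins. Of the genes, 307 were called in opposite directions in the clones. Of 163 named genes 123 differed between the clones, against 26.5% of all 9564 tested genes. Most named genes were picked for large or clear changes in these same libraries, which raises their share.

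Of the splits of the libraries, the real ones included, 1 of 10 gave as many genes as the real 1985 for KO1, 1 of 10 as the real 2152 for KO2 and 1 of 10 as the real 2533 between clones, with 0 genes as the highest other in each, and 10 splits are too few for a share under 0.05. For the average of both clones 3 of 100 splits, out of 840 possible, gave as many as the real 1860. Libraries were not assigned to groups at random, so this count excludes no difference between clones that arose by chance. It shows that the groups differ, and not that the control differs from the clones more than they differ from each other. The highest other was 2544, with KO2 in the control's place, and KO1 there gave 2313. The 3 splits along whole groups were included on purpose, so 3 of 100 is no share of random splits, and the real split gave the fewest calls of these 3. The 97 random ones reached 1218, which points to a structure of the samples: each group stands apart from the others.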

How the results depend on the processing

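The tests chosen only after the data were seen were edgeR quasi-likelihood, the FPKM tables and the exclusion of chromosome 12 and distal 16. Gene counts stayed within 1.5 times the reported ones except with DESeq2 (KO1 1236, KO2 1396, between clones 1612, average 1126, shared 430) and with edgeR against a fold of 1.5 (349, 421, 461, 255 and 116), a stricter question by construction. DESeq2 placed 7609 of 9564 gene-wise dispersions at their lower bound, with a median fitted dispersion of 0.0103 against 0.000348 in edgeR. Leaving out 1 library gave 1674 to 2029, 1840 to 2171, 2179 to 2529, 1470 to 1778 and 581 to 666. With the replicate block the counts were 2001, 2171, 2545, 1885 and 724, and without chromosome 12 and distal 16 they were 1748, 1940, 2152, 1725 and 690, with 9155 genes tested. The FPKM tables give no value for the average. The balance of higher and lower calls moved with the scaling. With library size only KO1 had 877 higher and 1238 lower, KO2 924 and 1243, between clones 1347 and 1211, shared 334 and 432. With upper quartile scaling these were 929 and 1103, 1132 and 1037, 1503 and 1112, and 375 and 328. Leaving out chromosome 12 and distal 16 gave 981 and 767, 839 and 1101, 896 and 1256, and 370 and 320. Of 322 called results for named genes 136 lost their call somewhere and 186 were the same under each alternative run for them, none turning direction. Only 280 were tested under all 25 alternatives, of which 156 were the same throughout: 292 could be tested without chromosome 12 and distal 16, 310 with at least 10 CPM in 3 libraries and 317 after thinning. Zscan10, with 0 reads, could not be tested. Depth limits genes near the filter.

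Of 35 list calls 22 were the same under every alternative. The values that follow are adjusted p of lists, and the cause was not tested. With an estimated correlation calls were lost in KO1 for oxidative phosphorylation at 0.104 and unfolded protein at 0.104. In KO2 they were lost for osteoclast inhibitory factors at 0.0654, MHC class II at 0.0501, LXR at 0.0879, glycolysis at 0.403 and ribosomal at 0.491. Between clones they were lost for NF-kB at 0.131, macrophage at 0.224, MHC class II at 0.105, oxidative phosphorylation at 0.324, haem at 0.0562 and ribosomal at 0.224. With fry, which asks only whether a list's genes move 1 way on balance, other lists were called. Calls were gained upward in KO1 for osteoclast inhibitory factors at 0.000613, p53 at 0.00743 and adhesion at 0.0049. Downward calls were gained in KO1 for NF-kB at 0.00277, MHC class II at 0.000269 and G2 and M phase at 0.0155. In KO2 calls were gained upward for osteoclast drivers at 0.000785, lysosome at 0.00338 and adhesion at 0.00359. Downward calls were gained in KO2 for G2 and M phase at 0.0159, cholesterol at 0.0483, haem at 4.83e-06 and immediate early at 0.0417. Between clones calls were gained with KO2 higher for osteoclast drivers at 0.00437, S phase at 0.0315 and LXR at 0.020. With KO2 lower they were gained for lysosome at 0.0387, p53 at 0.00859 and immediate early at 0.020. Directions turned with fry in KO1 for S phase at 0.668. Between clones they turned with fry for osteoclast effectors at 0.0284, NRF2 at 0.0208 and adhesion at 0.616. Under library-size scaling the macrophage call between clones was lost at 0.0508. Directions under that scaling turned in KO1 for S phase at 0.908. In KO2 they turned for immediate early at 0.964. With the replicate block the NF-kB call between clones was lost at 0.0539. There the direction turned between clones for NRF2 at 0.9977. With at least 10 CPM in 3 libraries directions turned in KO1 for immediate early at 0.905. In KO2 they turned for p53 at 0.963. Between clones they turned for adhesion at 0.921. Without chromosome 12 and distal 16 calls were lost between clones for macrophage at 0.0768 and oxidative phosphorylation at 0.077. Directions without them turned in KO1 for osteoclast drivers at 0.882, S phase at 0.98 and immediate early at 0.773. In KO2 they turned for p53 at 0.912. Leaving out each library in turn changed a call or a direction for some lists. In KO1 the ranges were S phase 0.618 to 0.955 and p53 0.034 to 0.115. In KO2 the ranges were osteoclast inhibitory factors 0.0121 to 0.0595, glycolysis 0.00521 to 0.0738, p53 0.643 to 0.993, immediate early 0.767 to 0.997 and ribosomal 0.000293 to 0.0569. Between clones the ranges were NF-kB 0.036 to 0.0894, macrophage 0.0256 to 0.0738, oxidative phosphorylation 0.0144 to 0.0638, NRF2 0.848 to 0.964 and p53 0.045 to 0.231. The p53 list was called without Control replicate 3 in KO1 and without KO2 replicate 3 between clones, each the lowest value given.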

Other observations

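Some fixed lists had fewer than 5 tested members and were not tested as lists. Of the pluripotency network, Fbxo15 rose in both clones (log2 change 1.54 ± 0.35 in KO1 and 1.43 ± 0.35 in KO2) and the DNA methylation cofactor gene Dnmt3l rose in KO2 (1.47 ± 0.30, and 0.21 ± 0.30 in KO1, not called). Klf4 was higher in KO2 (0.79 ± 0.28), a call lost under 10 of 24 alternatives. These were DESeq2 (adjusted p = 0.198), no filter (0.0717), thinning (0.0685), the FPKM tables (0.0534), edgeR against a fold of 1.5, an adjusted p under 0.01, and leaving out Control replicate 1 or 3 or KO2 replicate 2 or 3. That made 1 of 3 members in KO1, 3 of 3 in KO2 and 1 of 3 between the clones. Among markers of other cell types the granulocyte receptor gene Csf3r fell in both clones (-2.13 ± 0.29 and -2.52 ± 0.29), 1 of 2 granulocyte markers. Vim, an intermediate filament gene that RAW264 controls also express at 1013 ± 6.07, was the only tested fibroblast marker and rose in both (0.66 ± 0.037 and 1.15 ± 0.037). Of 4 dendritic cell markers 1 rose and 1 fell in KO1, the latter being Irf4 (-1.45 ± 0.47), and 3 fell in KO2, with Tcf4 at -1.01 ± 0.092 there. The Irf4 call in KO1 was lost under 7 of 23 alternatives: pseudocount 0.1 (adjusted p = 0.154), no filter (0.0576), DESeq2 (0.0518), edgeR against a fold of 1.5 (0.0581), an adjusted p under 0.01, and leaving out Control replicate 3 (0.139) or KO1 replicate 2 (0.0931). Between the clones Vim was higher in KO2 (0.49 ± 0.037), 2 of 4 dendritic cell markers were lower, and 1 of 2 granulocyte markers, Cxcr2, was higher (0.65 ± 0.25). The Cxcr2 call was lost under 15 of 25 alternatives. These were DESeq2 (adjusted p = 0.198), limma-voom (0.0559), only the groups compared (0.062), pseudocount 0.1 (0.0548), no filter (0.103), the FPKM tables (0.097), chromosome 12 and distal 16 left out (0.0516), edgeR against a fold of 1.5, an adjusted p under 0.01, and leaving out Control replicate 1 or 2, KO1 replicate 1 or 3, or KO2 replicate 2 or 3. The lists of B cell, T and NK cell, mast cell and epithelial and endothelial markers had 0 tested members, and 0 of the 26 mitochondrially encoded genes were listed in the table.

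Genes with at most 3 reads over a group and at least 10 CPM in another numbered 12 in KO1 against control (6 with 0 reads) and 14 in KO2 against control (10 with 0 reads). Of the genes expressed in KO1, 15 were this low in KO2, and of those expressed in KO2, 3 were this low in KO1. In control 1 gene expressed in KO1 and 3 expressed in KO2 were this low. In a principal component analysis of the libraries the first component held 44.8% and the second 31.8% of the variance, and the 3 groups lay apart.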
